A study of Mus musculus with 6 samples.

How the data were processed

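RNA sequencing libraries (TruSeq Stranded Total RNA, paired reads on a NovaSeq instrument) were made from 6 samples of the mouse cell line NMuMG, 2 per group, grouped by the genotype in the labels as control, Serpine1 overexpression and Tra2b overexpression. Tra2b as a group stands here for the libraries with that label, in which Tra2b was not raised. The deposited values are expected counts per gene, not scaled, for 62228 features of the FASTDB annotation with mm39 coordinates, and between 38.7% and 40.2% of the values of a library were not whole numbers (tolerance 0.001). The submitters' notes name HISAT2 for alignment and limma without a stated role. No version, counting tool or strand setting is given in the sources used here. Total counts ran from 59890591 to 80876677 per library. The reference tables at hand belong to other mouse builds and were used for names and gene classes only, so positions and identifiers come from the table itself. Of the features, 25187 carry a symbol and 37041 do not.

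Counts were rounded and analysed with edgeR (version 4.0.16 in R version 4.3.3). Genes were kept by filterByExpr with the groups, which left 23021 genes, 13819 with a symbol and 9202 without. Of these, 167 merge more than 1 symbol. Libraries were scaled by TMM (factors 0.9456 to 1.031), and counts per 1000000 (CPM) use the scaled library sizes. A quasi-likelihood model with 1 coefficient per group was fitted to all 6 libraries with robust settings (common coefficient of variation 18.9%, residual degrees of freedom 3, median prior degrees of freedom 5.32), and 3 comparisons were tested, 2-sided, with Benjamini-Hochberg adjustment over all genes tested in each and a threshold of 0.05. Values are given as mean ± SD of 2 libraries. For a gene without a count in a group, the fold is a lower bound against a floor of 3 counts over both libraries of the group. The replicates of a group were checked and are not copies of each other. As chi-square per degree of freedom, the variance between them was 16.3, 84.6 and 55.3 times that of counting error. These values are for control, Serpine1 and the libraries labelled Tra2b overexpression.

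23 gene lists were fixed before the data were examined, and the 22 with at least 5 tested members were tested with camera of limma (version 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, 2-sided. Beside it, camera with an estimated correlation and fry were run. With an estimated correlation 2, 2 and 0 lists passed in Serpine1 against control, Tra2b against control and Serpine1 against Tra2b, in place of 8, 6 and 8. With fry 2, 6 and 5 lists passed in the same order. The lists covered epithelial junctions, mesenchymal genes, the TGF-beta response, collagens and matrix, plasminogen activation, splicing regulators, interferon-stimulated genes, MHC class I presentation, cytokines, S phase, G2/M phase, replication-dependent histones, p53 targets, cholesterol, glycolysis and hypoxia, the unfolded protein and integrated stress response, actin and adhesion, Wnt and Notch, luminal markers, basal markers, markers of fibroblasts, endothelium and blood cells, and heat shock and immediate early genes. Serpine1 and Tra2b were left out of every list. The list of mitochondrially encoded genes could not be tested, since the 13 features of that chromosome carry no symbol, and their share of the counts is given in its place.

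The genes named in the text follow a rule also fixed before the data were examined. It takes Serpine1 and Tra2b, 8 genes of the epithelial-mesenchymal transition whether called or not, and for each comparison up to 8 rises and 8 falls. These are the largest by log2 fold change among genes that passed, with a mean of at least 2 CPM, both libraries of one group above both of the other and a plain symbol. It adds up to 3 members with the smallest adjusted p of each list with at least 3 called members. Any other gene is named as chosen after its values were seen.

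The alternatives fixed in advance were size factors as in DESeq2 (RLE), library totals alone, no filter, a filter of at least 50 counts in 2 libraries, DESeq2 (version 1.42.0), limma-voom, only the 4 libraries compared, the replicate number as a block, each library left out in turn, libraries thinned to the lowest total, introduced, mitochondrial and small RNA genes left out of library sizes, and, for counts of genes, a log2 fold change of at least 1. Added after the data were seen were Serpine1 2 and Tra2b 2 left out together, a covariate for the mean of the cell cycle lists, the replicate block with control numbers crossed, and, for the overlap of calls, 1 control library for each comparison. The overlap of calls was compared with 20 simulations of unchanged groups.

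The fit was tested on counts simulated from the control means and 1 dispersion per gene, with 200 of 23021 genes changed per comparison. For Serpine1 against control it recovered 98% of 4-fold and 59% of 2-fold changes, and 21 of its 178 calls were false. For Tra2b against control the values were 95% and 57%, with 23 of 175 calls false, so the share of false calls exceeded the nominal level and calls near the threshold carry that risk. A list of 40 genes with a planted 1.5-fold rise had a camera p of 3.79e-45 and a fry p of 0.000594. One list without a change had 0.651 and 0.527. The simulated genes varied independently, so this does not test lists whose members vary together. All simulated groups also had the same dispersion, without the differences in replicate spread between the measured groups. The shares of recovered and false calls may therefore not hold for the measured libraries.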

Results

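Gene expression was measured by RNA sequencing in NMuMG cells, an epithelial line from normal mouse mammary gland that is widely used to study the epithelial-mesenchymal transition. The 6 libraries form 3 groups of 2: control cells, cells labelled as given Serpine1 by a lentivirus and cells labelled as given Tra2b by a retrovirus. Serpine1 encodes plasminogen activator inhibitor 1, and Tra2b encodes a splicing regulator. The series title asks whether Serpine1 mRNA acts on this transition as an RNA, apart from its protein. The libraries were made from total RNA, and the table gives estimated counts for 62228 features with mm39 coordinates. Total counts were 60245943 and 59890591 in control 1 and control 2, 61462018 and 72401414 in Serpine1 1 and Serpine1 2, and 80876677 and 73425150 in Tra2b 1 and Tra2b 2. The ribosomal RNA feature took from 16.49% of the counts in Serpine1 2 (95% Wilson interval 16.48% to 16.49%) to 19.54% in control 1 (19.53% to 19.55%). Features of the mitochondrial chromosome took from 1.80% in control 1 (1.79% to 1.80%) to 2.52% in Serpine1 2 (2.52% to 2.52%). Such intervals, and the floors used for groups without a count, cover counting error only. The p-values measure the spread between these samples, and the labels do not say whether the replicates of a group were separate cultures. The labels also do not say whether control cells received an empty virus, so every difference from control may include an effect of the virus.

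Serpine1 was raised in the libraries labelled Serpine1 overexpression, and Tra2b was not raised in the libraries labelled Tra2b overexpression. Serpine1 (GSMG0043161, mm39 chromosome 5, 137090358 to 137101126) stood at 91.9 and 92.3 counts per 1000000 (CPM) in control, 686 and 619 CPM in the Serpine1 libraries and 80.1 and 58.1 CPM in the libraries labelled Tra2b overexpression. It rose by a log2 fold change of 2.83 (SE 0.16, n = 2 per group) against control, a 7.09-fold rise with an adjusted p of 5.87e-05. Tra2b (GSMG0035291, mm39 chromosome 16, 22063303 to 22084755) stood at 38.5 and 41.9 CPM in control, 41.6 and 32.3 CPM in the Serpine1 libraries and 36.2 and 32.5 CPM in the libraries labelled Tra2b overexpression. Its log2 fold change in the latter against control was -0.23 (SE 0.14, adjusted p = 0.459), and the 95% interval of the fold ran from 0.683 to 1.07. The table gives 1 value per gene, so reads from an introduced copy that lacks the counted parts of Tra2b would not be seen. Serpine1 itself differed from control by -0.41 (SE 0.15, adjusted p = 0.178) in the libraries labelled Tra2b overexpression, and -0.66 without Tra2b 1 (adjusted p = 0.049, with 0.00803 to 0.622 over all settings tried). Where 1 library is left out, here and below, its group keeps 1 library, so the p takes its spread from the other groups alone and assumes that the lone library varies like them.

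**Figure D1:**
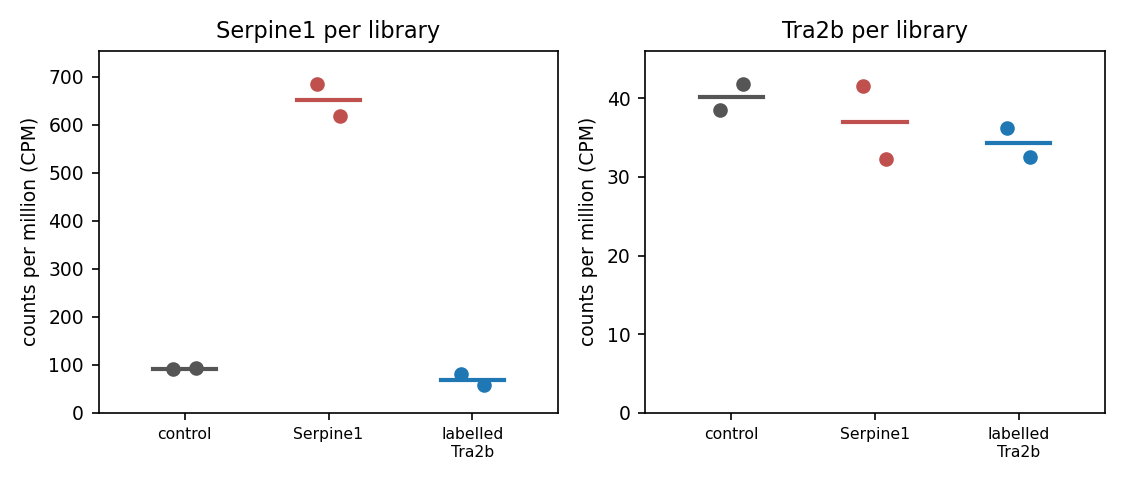
CPM of Serpine1 and Tra2b in each of the 6 libraries (points), with the mean of each group of 2 (lines). Serpine1 stood at 686 and 619 CPM in the Serpine1 libraries against 91.9 and 92.3 CPM in control, while Tra2b lay between 32.3 and 41.9 CPM in all 6.

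Serpine1 overexpression against control compares cells given the Serpine1 lentivirus with control cells, in which a virus is not stated. Genes induced by type I interferon fell together: of 47 tested members of that list, 45 fell and none rose. The median log2 fold change was -3.70, a 12.96-fold fall. Cxcl10, a chemokine that attracts T cells, went from 188 ± 34.7 CPM (SD, n = 2) in control to 1.74 ± 0.265 CPM, a log2 fold change of -6.76 (SE 0.41). Ccl5, another chemokine of the antiviral response, fell by 6.21 (SE 0.38) on the log2 scale. Ifit1, which binds viral RNA, went from 833 ± 134 CPM to 13.3 ± 4.51 CPM, and Isg15, a ubiquitin-like modifier, from 150 ± 17.2 CPM to 1.99 ± 1.26 CPM. The antiviral enzyme Rsad2 had a log2 fold change of -6.36 (SE 0.48), and Ifit1bl1, Ifit1bl2, Ifit3 and Ifit3b had values from -6.41 to -5.86. Bst2, which tethers budding virus, and Parp12 fell less, with -3.00 (SE 0.11) and -3.18 (SE 0.12).

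The list's call held with an estimated correlation (adjusted p = 0.0124), and adjusted over the list alone 46 members fell and 1 rose. The 2 members without a call over all genes were Ifi27 (25.6 CPM in control, 41.7 CPM with Serpine1, log2 fold change 0.70, adjusted p = 0.11) and Oas3 (163 CPM and 12.6 CPM, log2 fold change -3.69, adjusted p = 0.179), both named after their values were seen. The list took 0.671% (95% Wilson interval 0.669% to 0.673%) and 0.586% (0.584% to 0.588%) of all counts in control 1 and control 2. It took 0.0661% (0.0654% to 0.0667%) and 0.0718% (0.0712% to 0.0724%) in Serpine1 1 and Serpine1 2.

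Genes that load and present peptides on MHC class I fell as well. Of 20 tested members, 15 fell and none rose (16 fell adjusted over the list alone), with a median log2 fold change of -1.60. H2-K1, a class I heavy chain, fell from 66.3 ± 6.63 CPM to 20.3 ± 0.388 CPM, a log2 fold change of -1.71 (SE 0.13). H2-Q4 had -1.83 (SE 0.13) and the merged feature H2-D1 // H2-L had -1.30 (SE 0.12). The 5 members without a call, named after their values were seen, were H2-Q7, H2-T23, Pdia3, Tapbpl and Calr, with log2 fold changes of -2.35, -0.26, -0.10, -0.45 and -0.30. The list passed at an adjusted p of 1.28e-54, and at 0.043 with an estimated correlation.

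Few genes rose. Besides Serpine1 these were Aldoc, a glycolytic aldolase, with a log2 fold change of 1.15 (SE 0.19), Clic3, a chloride channel protein, with 1.11 (SE 0.19), Rnu12, a spliceosomal RNA, with 0.91 (SE 0.15), Mturn with 0.91 (SE 0.16) and Tmsb4x, an actin-binding peptide, with 0.63 (SE 0.11). The glycolysis and hypoxia list was called higher (median log2 fold change 0.41, adjusted p = 5.8e-09), with Aldoc as the 1 riser among 34 members and 13 risers adjusted over the list alone. That list had an adjusted p of 0.407 with an estimated correlation. Its rise was uneven between the replicates. The mean log2 CPM of its members, centred on the 6 libraries, was 0.471 in Serpine1 1 and 0.0799 in Serpine1 2. It was -0.201 in control 1 and -0.174 in control 2.

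5 further lists were called with small medians and lost the call with an estimated correlation. Collagens and extracellular matrix (median log2 fold change 0.18, adjusted p = 0.0234), TGF-beta response (0.08, adjusted p = 0.0329) and basal and myoepithelial markers (0.19, adjusted p = 0.0442) were called higher, each without a called member among 37, 32 and 14. Their adjusted p was 0.407 with an estimated correlation. Adjusted over the list alone, 2 collagen list members rose (Plod2, log2 fold change 0.53, and Lamb3, 0.47) and 1 basal marker (Krt14, 1.61), named after their values were seen, and no TGF-beta response gene. Cytokines and chemokines were called lower (median -0.10, adjusted p = 0.0329, and 0.407 with an estimated correlation). In that list Ccl7 (log2 fold change -0.98) and Tnfsf10 (-5.08) fell, and adjusted over the list alone 3 fell, with Il6, and 1 rose, Saa3, all named after their values were seen. S phase and DNA replication genes were called lower (median -0.45, adjusted p = 0.00754) with no called member among 49, none adjusted over the list alone, and an adjusted p of 0.868 with an estimated correlation. That call rested on Serpine1 2, in which these genes were 1.33 lower on the log2 scale than in Serpine1 1, as the values by replicate show. Without Serpine1 2 the direction turned (adjusted p = 0.381), and without control 2 the adjusted p was 0.061 (1.17e-17 to 0.868 over all settings tried). The collagen, TGF-beta, cytokine and basal lists also lost their calls without Serpine1 2 (adjusted p = 0.136, 0.146, 0.123 and 0.123). The collagen and TGF-beta lists lost them without control 2 (0.061 for both), and the cytokine and basal lists without control 1 (0.0905 and 0.146).

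The other 14 tested lists were not called. Among them, Tmsb4x rose in the actin, adhesion and migration list of 48, and Xdh (log2 fold change -1.28) and Muc1 (-0.68) fell among 12 luminal and lactating markers. Zfp36 (-0.65) fell among 37 heat shock and immediate early genes. Xdh, Muc1 and Zfp36 were named after their values were seen. No member was called among 31 epithelial junction genes (median 0.02), 28 mesenchymal genes (0.15), 20 plasminogen activation genes (0.18), 58 splicing regulators (-0.08), 53 G2/M genes (-0.29), 54 histone genes (-0.24), 32 p53 targets (0.10), 25 cholesterol genes (0.05), 40 stress response genes (-0.01), 26 Wnt and Notch genes (0.20) or 9 markers of fibroblasts, endothelium and blood cells (-0.11). The test's direction was opposite to the median for the luminal markers (0.07, test lower). The mean was opposite to the median for the mesenchymal (-0.13), plasminogen (-0.01) and luminal (-0.02) lists.

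In total 227 of 23021 tested genes passed the edgeR test, 6 higher and 221 lower with Serpine1 overexpression, and 2002 had an unadjusted p under 0.05. Of these, 3 rose at least 2-fold, namely Serpine1, Aldoc and Clic3, and 199 fell at least 2-fold. The count was 121 without control 1, and between 157 and 239 without any other single library. It was 393 with DESeq2 and, in alternatives chosen after the data were seen, 470 with the crossed replicate block, 1651 with a covariate for the cell cycle lists and 3571 without Serpine1 2 and Tra2b 2. Of the 19 named genes called besides Serpine1, 8 missed the threshold without control 1, 7 without control 2, 8 without Serpine1 1, and 6 each without Serpine1 2, Tra2b 1 and Tra2b 2. The rises of Clic3, Rnu12, Mturn and Tmsb4x were among those lost in all 6 omissions, and that of Aldoc in 5.

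**Figure D2:**
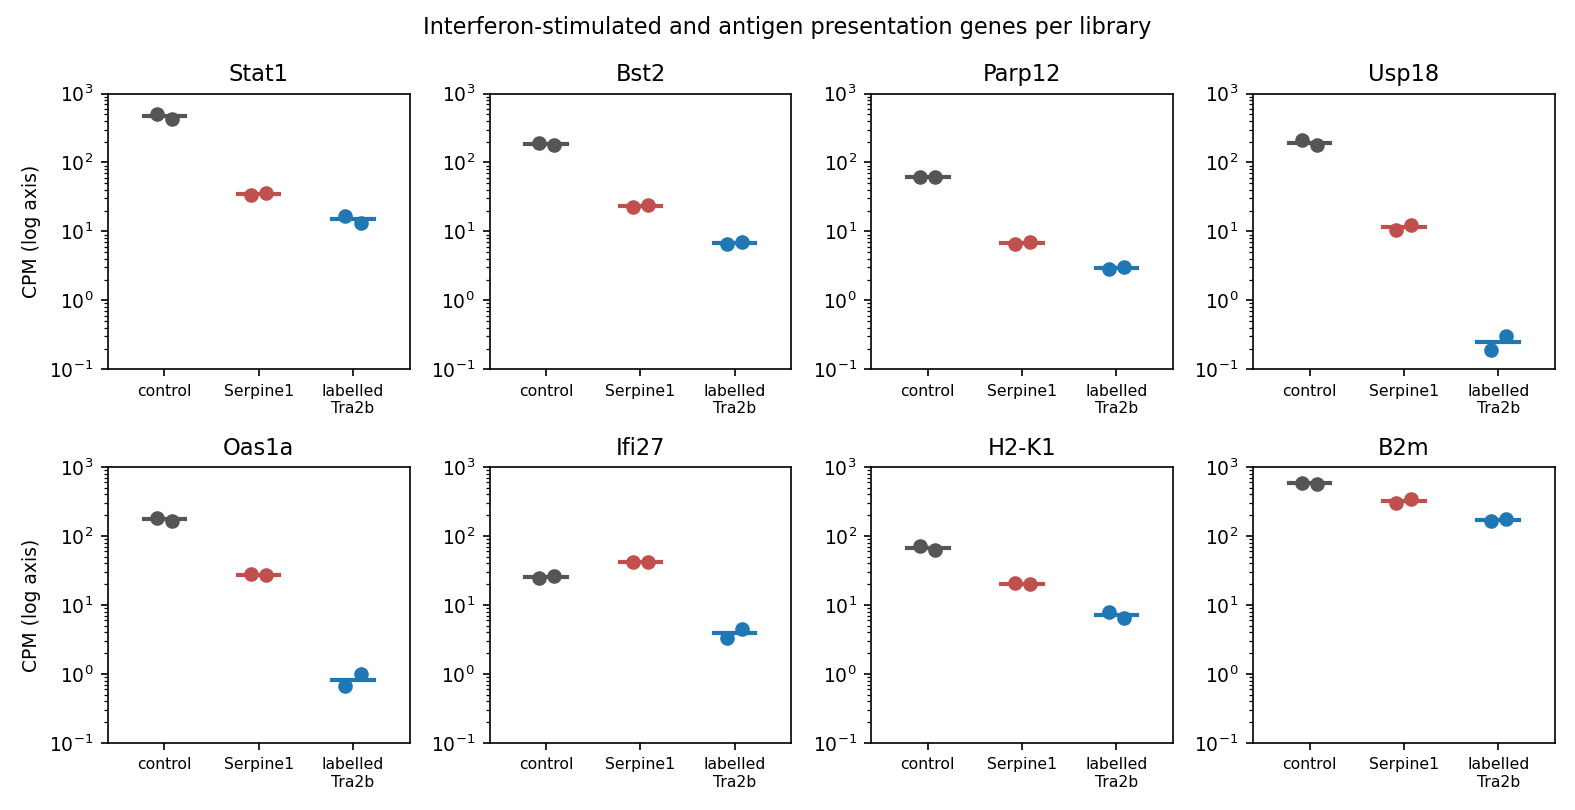
CPM, on a log axis, of 6 interferon-stimulated genes and 2 antigen presentation genes in each library (points), with the mean of each group of 2 (lines). All but Ifi27 were highest in both control libraries, and all 8 were lowest in both libraries labelled Tra2b overexpression.

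The libraries labelled Tra2b overexpression were also compared with control, with the limit that Tra2b itself was not raised in them. The counts do not show that the Tra2b construct was present, so a difference here cannot be assigned to it. All 47 tested interferon-stimulated genes fell, with a median log2 fold change of -6.61, also with genes at 0 counts set to their bound. Ifi44, Oas2, Iigp1, Trim30a, Ifit1bl1, Sp100, Oasl2 and Gvin1 had no count in either library, against means from 24.7 to 152 CPM in control. With a floor of 3 counts over both libraries, Ifi44 was at least 7860-fold lower, Oas2 at least 5580-fold, Iigp1 at least 5370-fold and Trim30a at least 4240-fold. The bounds were 3600-fold for Ifit1bl1, 2480-fold for Sp100, 2320-fold for Oasl2 and 1280-fold for Gvin1. Usp18, which dampens interferon signalling, fell from 194 ± 22 CPM (SD, n = 2) to 0.247 ± 0.0811 CPM, Ifit3b had a log2 fold change of -9.36 (SE 0.23) and Bst2 one of -4.79 (SE 0.12). The list's adjusted p was 0.0198 with an estimated correlation, and all 47 also fell adjusted over the list alone. It took 0.0232% (95% Wilson interval 0.0229% to 0.0236%) and 0.0238% (0.0234% to 0.0241%) of the counts in Tra2b 1 and Tra2b 2.

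Of the 20 MHC class I genes, 16 fell (19 adjusted over the list alone), with a median log2 fold change of -2.44 and an adjusted p of 0.0378 with an estimated correlation. H2-K1 had -3.21 (SE 0.14), H2-Q4 -2.73 (SE 0.14) and H2-D1 // H2-L -2.11 (SE 0.12). The 4 without a call, named after their values were seen, were H2-Q7, Pdia3, Tapbpl and Calr, and of these Tapbpl (log2 fold change -0.16) was also without a call adjusted over the list alone.

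The largest rise under the naming rule was that of Krt6a, a keratin of stressed and wounded epidermis, which went from 0.328 ± 0.181 CPM to 13.8 ± 3.25 CPM, a log2 fold change of 5.39 (SE 0.51). The prolactin-family genes Prl2c2 and Prl2c3 // Prl2c4 rose by 3.55 (SE 0.36) and 3.80 (SE 0.57), and Sprr1a, a cornified envelope protein, by 2.50 (SE 0.32). Hal, which breaks down histidine, rose by 3.25 (SE 0.23), the kinase Camk1d by 2.96 (SE 0.44), the serpin Serpinb5 by 2.57 (SE 0.20) and the junction molecule Jam2 by 2.50 (SE 0.24). Prl2c2 and Prl2c3 // Prl2c4 are near-identical copies, as are Ifit3 and Ifit3b and several class I genes, so the division of counts between such copies is uncertain.

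Epithelial junction and identity genes were called higher (median log2 fold change 0.31, adjusted p = 4.2e-05), though at 0.369 with an estimated correlation. In that list 6 of 31 members rose and none fell (10 rose adjusted over the list alone). Among them were Krt7 (3.29, SE 0.42), the desmosomal plakophilin Pkp3 (2.24, SE 0.28) and Mal2 (1.06, SE 0.18). Krt7 and Pkp3 were scarce, at 0.338 and 0.880 CPM in control and 3.32 and 4.17 CPM here. The more abundant Krt19 (713 CPM in control, 0.86) and Spint2 (210.5 CPM, 0.43), named after their values were seen, rose less. In the mesenchymal list, which was not called (median -0.07, adjusted p = 0.275), 5 of 28 fell and 2 rose (8 and 4 adjusted over the list alone). Those that fell were Snai1, a repressor of epithelial genes, with -1.45 (SE 0.29), the receptor Axl with -0.89 (SE 0.11), Thbs1 with -0.99 (SE 0.15), and Pdgfrb and Fap. The last pair stood at only 0.198 and 0.312 CPM in control. Those that rose were Mmp14 (0.63) and Loxl2 (0.88). Pdgfrb, Fap, Mmp14 and Loxl2 were named after their values were seen, and Pdgfrb was also the 1 called member, lower, among 9 markers of fibroblasts, endothelium and blood cells (median -0.26, adjusted p = 0.237).

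Collagens and extracellular matrix genes were called lower (median -0.16, adjusted p = 0.0344, and 0.369 with an estimated correlation), with 6 of 37 lower and 1 higher (11 and 5 adjusted over the list alone). Col6a1 had a log2 fold change of -1.84 (SE 0.18), Col5a1 -1.67 (SE 0.18) and the protease Adamts1 -1.35 (SE 0.16), while Col4a2, named after its value was seen, rose by 0.43. Cytokines and chemokines were called lower (median -0.31, adjusted p = 0.0192, and 0.369 with an estimated correlation), with 8 of 29 lower and 1 higher (11 and 1 adjusted over the list alone). Tnfsf10, a death receptor ligand, had no count and was at least 133-fold lower, and Ccl7 had -1.01 (SE 0.13), while the acute phase gene Saa3 rose by 2.03 (SE 0.14). p53 targets were called lower (median -0.25, adjusted p = 0.00593, and 0.244 with an estimated correlation), with 5 of 32 lower and none higher (7 lower adjusted over the list alone). These were Ephx1 (-1.03, SE 0.12), the cyclin Ccnd2 (-1.61, SE 0.20), Psrc1 (-0.74, SE 0.13), and Fas (-1.25) and Eda2r (-2.45), the last pair named after their values were seen. With fry the collagen, cytokine and p53 lists kept their calls (adjusted p = 0.0239, 0.0239 and 0.00475). The epithelial junction list lost its call with fry (adjusted p = 0.0684), and the luminal markers gained one, lower (adjusted p = 0.0498).

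Some lists without a call had called members. Of 32 TGF-beta response genes (median -0.17, adjusted p = 0.338), Tgfbi (-2.54, SE 0.36), Tgfb3 (-1.31, SE 0.19) and Il11 (-1.96, SE 0.44) fell, and Smurf1, which degrades pathway components, rose (0.57). Il11 stood at only 0.559 CPM in control. Of 20 plasminogen activation genes (median 0.22, adjusted p = 0.524), Plau, the urokinase activator, fell by 1.31 (SE 0.17) on the log2 scale, with Tfpi (-2.04, SE 0.35), Plgrkt (-0.58, SE 0.12) and Itgb5 (-0.78) also lower, while Plat (0.54) and Serpinb6a (0.48) rose. Of 58 splicing regulators (median 0.07, adjusted p = 0.151), the SR protein kinase Srpk2 rose (0.74) and Tra2a, the paralog of Tra2b, fell (-0.49, adjusted p = 0.0412), though adjusted over the list alone only Srpk2 passed. Of 40 stress response genes (median -0.05, adjusted p = 0.625), the endoplasmic reticulum chaperone genes Pdia4 (-0.53, SE 0.10), Sdf2l1 (-0.98, SE 0.18) and Creld2 (-0.98, SE 0.20) fell and Dnajb9 (0.63) rose. Of 48 actin and adhesion genes (median 0.03, adjusted p = 0.237), the bundling protein Fscn1 fell (-1.26, SE 0.13), while Myh10 (1.68, SE 0.22), Itga6 (0.90, SE 0.14), Itgb4 (0.51, SE 0.10) and Flnc (0.76) rose. Itga6 and Itgb4 were also 2 of the 3 risers among 14 basal and myoepithelial markers, with Krt14 (1.79, SE 0.32), in a list that had an adjusted p of 0.109. Smurf1, Itgb5, Plat, Serpinb6a, Srpk2, Tra2a, Dnajb9 and Flnc were named after their values were seen.

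Wnt10a (-3.40, from 1.37 to 0.127 CPM) and Wnt7b (-0.66) fell among 26 Wnt and Notch genes. The median and mean of that list were -0.02 and -0.06 while the test pointed higher (adjusted p = 0.759). Xdh (-1.94) fell among 12 luminal markers (median -0.25), Ndrg1 (0.69) rose and Pfkfb4 (-0.83) fell among 34 glycolysis and hypoxia genes (median 0.15), and Ier3 (0.63) rose among 37 heat shock and immediate early genes (median -0.14). These 6 genes were named after their values were seen. No member was called among 49 S phase genes (median -0.35), 53 G2/M genes (-0.25), 54 histone genes (-0.54) or 25 cholesterol genes (-0.27).

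The edgeR test called 1195 of 23021 genes, 374 higher and 821 lower in the libraries labelled Tra2b overexpression, and 4298 had an unadjusted p under 0.05. At least 2-fold changes made up 144 rises and 641 falls. The count was 369 without control 1, 430 without control 2, 714 without Tra2b 1, 575 without Tra2b 2, 1623 without Serpine1 1 and 1593 without Serpine1 2. It was 1961 with DESeq2 and, in alternatives chosen after the data were seen, 2645 with the crossed replicate block, 4331 with the cell cycle covariate and 4695 without Serpine1 2 and Tra2b 2. Of the 51 named genes called, 18 missed the threshold without control 1, 16 without control 2, 12 each without Tra2b 1 and Tra2b 2, and 1 each without Serpine1 1 and Serpine1 2.

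**Figure D3:**
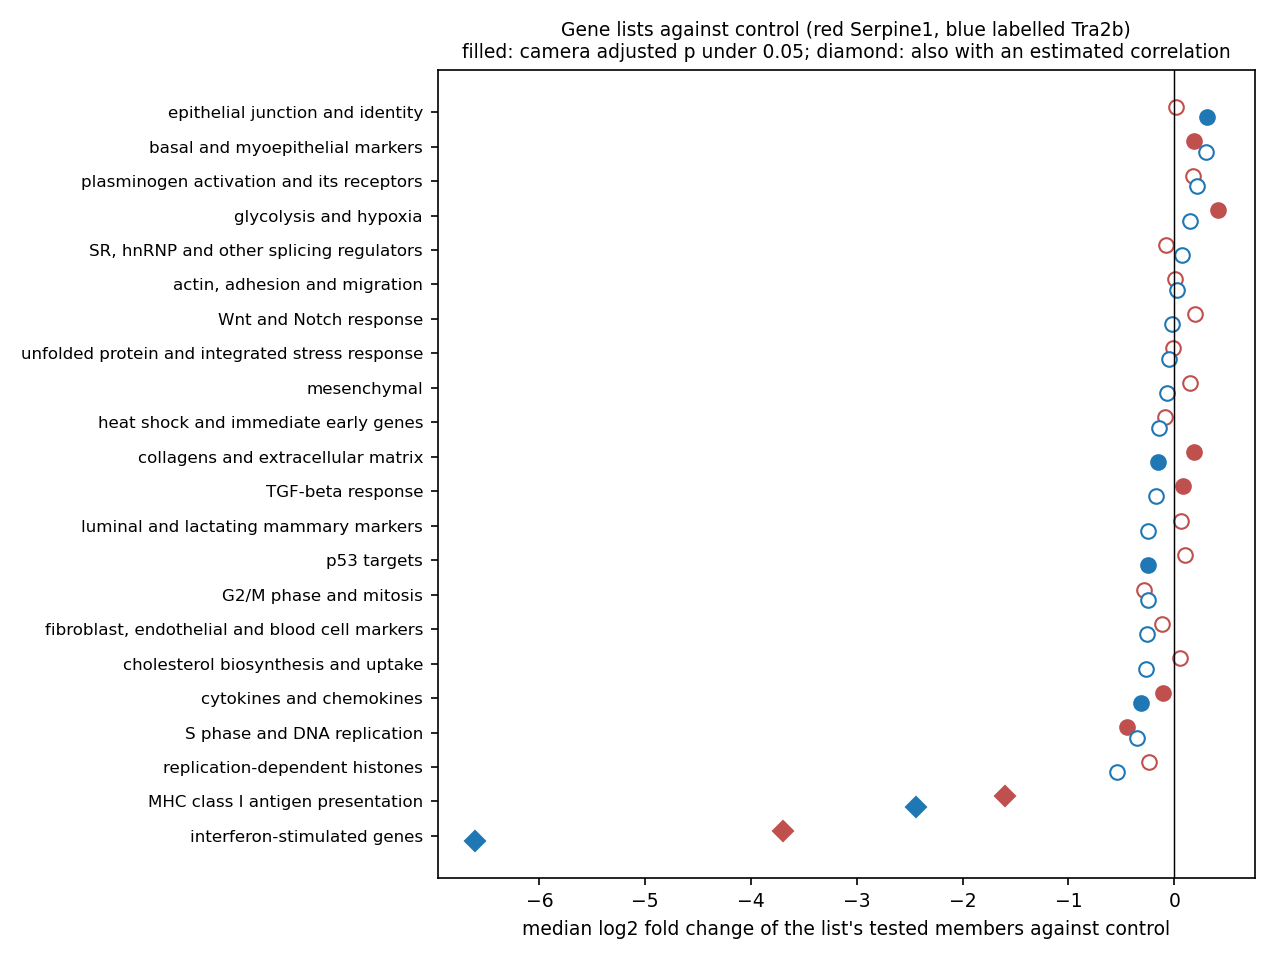
Median log2 fold change against control of the tested members of each of 22 gene lists, for Serpine1 overexpression (red) and the libraries labelled Tra2b overexpression (blue). Filled symbols passed camera at its preset correlation, and diamonds passed with an estimated correlation too, which only the interferon-stimulated and MHC class I lists did in both comparisons.

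Serpine1 overexpression against the libraries labelled Tra2b overexpression tests directly where these groups differ. By the labels both the introduced gene and the type of virus differ, and Tra2b was not raised, so a difference here cannot be assigned to either. Interferon-stimulated genes were higher in the Serpine1 libraries: 37 of 47 were called higher and none lower (42 higher adjusted over the list alone), with a median log2 fold change of 2.73. The list's call was lost with an estimated correlation (adjusted p = 0.0847) and held with fry (adjusted p = 0.00576). Of the other lists called in this comparison, fry kept MHC class I (adjusted p = 0.00576), collagens (0.011), TGF-beta response (0.0258) and p53 targets (0.00576). It did not keep epithelial junctions (0.0906), splicing regulators (0.282) or glycolysis and hypoxia (0.22). Oas2 stood at 9.06 ± 3.06 CPM (SD, n = 2) with Serpine1 and was at least 468-fold higher than in the libraries labelled Tra2b overexpression, where it had no count. The bounds were 401-fold for Trim30a, 229-fold for Ifi44, 173-fold for Sp100, 132-fold for Iigp1, 110-fold for Gvin1, 51.1-fold for Ifit1bl1 and 45.0-fold for Oasl2. Oas1a was higher by 5.06 (SE 0.19), Usp18 by 5.54 (SE 0.22) and Ifi27 by 3.41 (SE 0.16). Of 20 MHC class I genes, 11 were higher and none lower (13 higher adjusted over the list alone, median 0.91, adjusted p = 2.1e-15, and 0.119 with an estimated correlation), with H2-K1 at 1.5 (SE 0.14), the peptide transporter Tap2 at 3.67 (SE 0.35) and the light chain B2m at 0.91 (SE 0.11).

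Of 37 collagen and matrix genes, 11 were called higher with Serpine1 than in the libraries labelled Tra2b overexpression, none lower and 26 neither (15 and 3 adjusted over the list alone, median 0.42, adjusted p = 2.17e-06). The list's call was lost with an estimated correlation (adjusted p = 0.119). Col6a1 differed by 2.40 (SE 0.18), Col6a2 by 2.40 (SE 0.22) and Col5a1 by 2.00 (SE 0.18). TGF-beta response genes were called higher (median 0.39, adjusted p = 0.00283, and 0.143 with an estimated correlation), with Tgfb3 (1.31, SE 0.19) and Tgfbi (2.36, SE 0.36) higher and Smurf1 (-0.57, SE 0.13) lower among 32, and 13 higher and 2 lower adjusted over the list alone. Epithelial junction genes were called lower (median -0.29, adjusted p = 5.18e-05, and 0.336 with an estimated correlation), with 5 of 31 lower and none higher (7 and 1 adjusted over the list alone). These were Krt7 (-3.17, SE 0.41), Mal2 (-1.34, SE 0.18), Pkp3 (-1.41, SE 0.27), and Esrp2 (-0.72) and Dsp (-0.46), the last pair named after their values were seen. In the mesenchymal list, which was not called (median 0.16, adjusted p = 0.106), Thbs1 (1.35, SE 0.15), Snai1 (1.94, SE 0.29), S100a4 (1.21, SE 0.18), Axl (0.58) and Pdgfrb were higher and Prrx1 (-0.66) was lower among 28. Axl, Pdgfrb and Prrx1 are given here after their values were seen.

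p53 targets were called higher (median 0.27, adjusted p = 6.71e-05, and 0.119 with an estimated correlation), with 8 of 32 higher and none lower (9 higher adjusted over the list alone), among them Ephx1 (1.40, SE 0.12), Psrc1 (0.85, SE 0.13) and Perp (0.68, SE 0.11). Glycolysis and hypoxia genes were called higher (median 0.34, adjusted p = 0.00313, and 0.681 with an estimated correlation), with Mxi1 (0.82, SE 0.12), Aldoc (0.83, SE 0.18) and P4ha1 (0.71, SE 0.16) higher among 34 (7 higher and 2 lower adjusted over the list alone). The call was lost without Serpine1 1 (adjusted p = 0.383, with 3.33e-10 to 0.681 over all settings tried). Splicing regulators were called lower (median -0.14, adjusted p = 0.00313, and 0.681 with an estimated correlation), with Srpk2 (-0.76, SE 0.09), Fus (-0.71, SE 0.11), U2af1 (-0.63) and Rbm47 (-0.49) lower and Khdrbs3 (0.70, SE 0.13) higher among 58 (10 lower and 2 higher adjusted over the list alone). U2af1 and Rbm47 were named after their values were seen. That call was lost without Serpine1 2 (adjusted p = 0.116) and without Tra2b 1 (adjusted p = 0.151), with 2.05e-05 to 0.681 over all settings tried.

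Of the 8 named genes lowest with Serpine1 relative to the libraries labelled Tra2b overexpression, 5 were also among the 8 largest rises of the latter against control. Krt6a differed by -4.60 (SE 0.48), Hal by -4.15 (SE 0.24), Prl2c3 // Prl2c4 by -3.63 (SE 0.56), Prl2c2 by -2.92 (SE 0.35) and Camk1d by -2.81 (SE 0.43). Ptpru, a receptor phosphatase, differed by -2.82 (SE 0.26), Sprr2h by -2.64 (SE 0.28) and Anxa10 by -2.58 (SE 0.23). In lists without a call, Plau (1.47, SE 0.17), Itgb5 (1.06, SE 0.16), Tfpi (2.24, SE 0.35) and Plgrkt (0.53) were higher among 20 plasminogen genes. Cpb2 (-2.43) was lower, at 0.0884 CPM with Serpine1 and 0.491 CPM in the libraries labelled Tra2b overexpression. The median of that list was -0.03 and its mean -0.18 while the test pointed higher (adjusted p = 0.738). Cx3cl1 (1.14, SE 0.11), the macrophage growth factor Csf1 (1.82, SE 0.24), Ccl20 (1.33), Nfkb1 (0.55) and Il15 (1.1) were higher and Saa3 (-1.35, SE 0.13) lower among 29 cytokines (median 0.17). Fscn1 (1.65, SE 0.13) was higher, and Myh10 (-2.50, SE 0.23), Wasl (-0.64, SE 0.10), Ezr (-0.46), Itga6 (-0.68) and Flnc (-0.81) were lower, among 48 actin and adhesion genes, whose median was 0.01 and mean -0.03 (test lower). Wnt10a (3.83, SE 0.49), Wnt7b (0.83, SE 0.13) and the cyclin Ccnd1 (0.56, SE 0.12) were higher among 26 Wnt and Notch genes. Plgrkt, Cpb2, Ccl20, Nfkb1, Il15, Ezr, Itga6 and Flnc are given here after their values were seen.

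Ddit4 and Pdia4 were higher among 40 stress response genes, Xdh among 12 luminal markers, Lyz2 and Pdgfrb among 9 markers of fibroblasts, endothelium and blood cells, and Mylk among 14 basal markers, where Itga6 was lower. Ier3 was lower among 37 heat shock and immediate early genes, whose median (0.00) and mean (0.06) were above 0 while the test pointed lower. These genes were given after their values were seen. No member was called among the S phase (median -0.11), G2/M (-0.05), histone (0.27) and cholesterol (0.34) lists. The edgeR test called 1252 genes, 824 higher and 428 lower with Serpine1, of which 524 and 132 differed at least 2-fold, and 4739 had an unadjusted p under 0.05. The count was 415 without control 1, 418 without control 2, 401 without Tra2b 1, 440 without Tra2b 2, 845 without Serpine1 1 and 1308 without Serpine1 2. It was 404 with only the 4 libraries compared, 2258 with DESeq2 and, in alternatives chosen after the data were seen, 3110 with the crossed replicate block, 5365 with the cell cycle covariate and 5010 without Serpine1 2 and Tra2b 2. Of the 55 named genes called besides Serpine1, 10 missed the threshold without control 1, 10 without control 2, 5 without Serpine1 1, 3 without Serpine1 2, 17 without Tra2b 1 and 13 without Tra2b 2.

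Of 221 genes that fell with Serpine1, 214 (96.8%) also fell in the libraries labelled Tra2b overexpression, 60 of them in the interferon or MHC class I lists. Those lists leave out some interferon-induced genes that fell in both, such as Ifit1bl1, so 60 is not a full count of such genes. Independent sets of 221 and 821 genes, the falls of the 2 comparisons, would share 7.88, a value that leaves out the shared controls. In 20 simulations of unchanged groups that shared the control libraries at most 2 genes fell in both. No gene was changed in those simulations, so they give no expected overlap for lists of these sizes. Tested directly, 107 of the 214 were lower in the libraries labelled Tra2b overexpression than with Serpine1, and 1, Tanc2, was lower with Serpine1 (log2 difference -1.29, adjusted p = 0.0195). Only Rnu12 rose in both, by 0.91 with Serpine1 and 0.96 in the libraries labelled Tra2b overexpression, and up to 4 genes rose in both in the simulations of unchanged groups. Zfand2a (-0.83 with Serpine1 and 0.66 in the libraries labelled Tra2b overexpression), Hpgds (-0.66 and 0.87) and Mturn (0.91 and -0.70) were called in opposite directions. Tanc2, Zfand2a and Hpgds were named after their values were seen.

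Over 16711 genes the fold changes of both comparisons had a covariance of 0.299 against 0.0469 in the simulations, and a correlation of 0.710 against 0.499. Genes are not independent replicates, and both comparisons use the same 2 control libraries, so part of the excess may come from them. With 1 control library for each comparison, an alternative chosen after the data were seen, the covariance was 0.290 with control 1 for Serpine1 and control 2 for the libraries labelled Tra2b overexpression, and 0.269 with the controls exchanged (correlations 0.653 and 0.588). In these fits 148 of 155 and 116 of 118 genes that fell with Serpine1 fell in both. A departure common to both control libraries would remain in them. The shared count of 215 was 116 without control 1, and 324 with the crossed replicate block, 713 with the cell cycle covariate and 1059 without Serpine1 2 and Tra2b 2, the last 3 chosen after the data were seen.

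None of the 6 tested genes of the epithelial-mesenchymal transition fixed for this purpose was called in any comparison by the main edgeR test. At an unadjusted p under 0.05 these were 1 with Serpine1 against control (Vim), 2 in the libraries labelled Tra2b overexpression against control (Cdh1 and Fn1) and 2 in Serpine1 against the libraries labelled Tra2b overexpression (Fn1 and Vim), where DESeq2 called 0, 1 and 2 and limma-voom 0, 0 and 1. Cdh1, the adhesion molecule E-cadherin, stood at 252 ± 11.2 CPM (SD, n = 2) in control, 267 ± 38.5 CPM with Serpine1 and 312 ± 25.7 CPM in the libraries labelled Tra2b overexpression. Vim, the intermediate filament vimentin, stood at 1696 ± 50.7, 2083 ± 156 and 1564 ± 113 CPM in the same order. Its log2 difference between Serpine1 and control was 0.30 (SE 0.10, adjusted p = 0.43), and between Serpine1 and the libraries labelled Tra2b overexpression 0.41 (SE 0.10, adjusted p = 0.0569), where DESeq2 called it (adjusted p = 0.0387, with 1.81e-05 to 0.284 over all settings tried). Fn1, fibronectin, stood at 147 ± 14.8, 199 ± 90.1 and 56.5 ± 19.5 CPM, with -1.38 (SE 0.42, adjusted p = 0.197) in the libraries labelled Tra2b overexpression against control, where DESeq2 called it (adjusted p = 0.001, with 1.07e-16 to 0.6 over all settings tried), and 1.81 (SE 0.43, adjusted p = 0.109) with Serpine1 against them, where DESeq2 (adjusted p = 4.06e-06) and limma-voom (adjusted p = 0.0336) called it, with 2.07e-14 to 0.235 over all settings tried. Cdh2, N-cadherin, stood at 130 ± 0.806, 124 ± 17.1 and 136 ± 8.36 CPM, and the repressor Zeb1 at 6.74 ± 0.931, 5.95 ± 0.0619 and 6.35 ± 0.171 CPM. The repressor Snai2 stood at 3.39 ± 0.053, 4.59 ± 4.26 and 3.28 ± 2.61 CPM, with a wide spread between the replicates of the Serpine1 libraries and those labelled Tra2b overexpression. Epcam had 6 counts and Esrp1 2 counts in the 6 libraries together, too few to test. The intervals of the log2 fold changes with Serpine1 against control ran from -0.20 to 0.37 for Cdh1 and from -0.34 to 0.21 for Cdh2, but from -2.37 to 3.26 for Snai2. With a covariate for the cell cycle lists, chosen after the data were seen, 2 of the 6 genes passed for Serpine1 against control. It was 3 for the libraries labelled Tra2b overexpression against control and 3 for Serpine1 against these libraries. The covariate was taken from these same data and was lowest in Serpine1 2 and Tra2b 2, so it absorbs much of the spread within both groups. Leaving out Serpine1 2 and Tra2b 2 is near to the same adjustment and adds no separate support. The values that follow are those with the covariate. Against control with Serpine1, Vim passed as higher (0.36, adjusted p = 0.00173, with 1.22e-05 to 1 over all settings tried) and Snai2 as lower (-0.77, adjusted p = 0.0365, with 0.00222 to 1), opposite in sign to its main value. In the libraries labelled Tra2b overexpression against control, Cdh1 passed as higher (0.22, adjusted p = 0.0302, with 0.0282 to 0.747), and Snai2 (-1.03, adjusted p = 0.00163, with 0.000263 to 1) and Fn1 (-1.71, adjusted p = 5.88e-11) as lower. With Serpine1 against these libraries, Cdh1 passed as lower (-0.24, adjusted p = 0.0124, with 0.0119 to 0.747), and Vim (0.42, adjusted p = 5.54e-05) and Fn1 (1.73, adjusted p = 6.3e-11) as higher. With the crossed replicate block, also chosen after the data were seen, Cdh1 (adjusted p = 0.0464) and Fn1 (adjusted p = 0.004) passed in the libraries labelled Tra2b overexpression against control, and Vim (adjusted p = 0.00546) and Fn1 (adjusted p = 0.00176) in Serpine1 against these libraries.

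**Figure D4:**
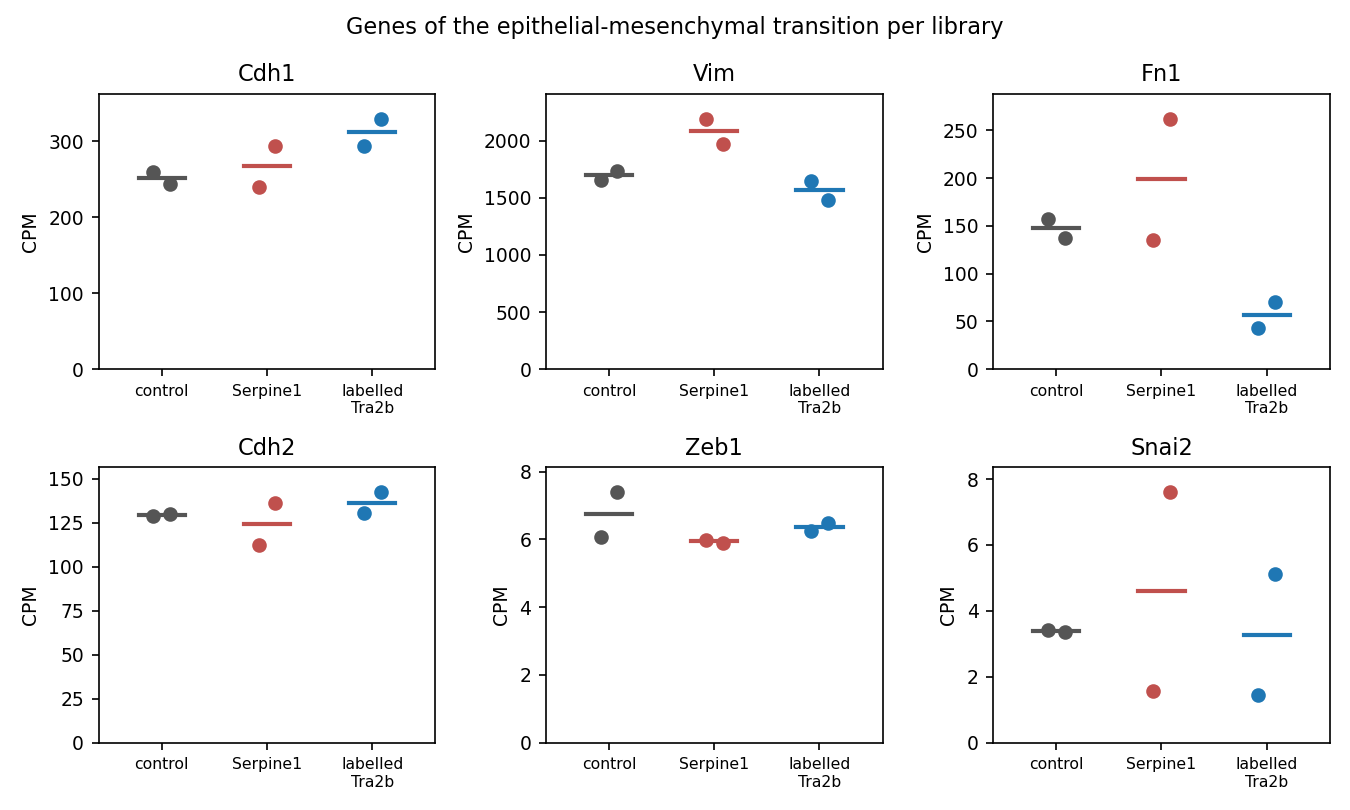
CPM of 6 genes of the epithelial-mesenchymal transition in each library (points), with the mean of each group of 2 (lines). Vim lay at 2083 CPM on average with Serpine1 against 1696 CPM in control, and none of the 6 passed the main edgeR test in any comparison.

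Cell cycle lists stood lower in replicate 2 than in replicate 1 of the Serpine1 libraries and those labelled Tra2b overexpression, without a test. The mean of the S phase list was 1.33 lower on the log2 scale in Serpine1 2 than in Serpine1 1 (difference of replicate 2 minus replicate 1, -1.33) and differed by -1.18 between Tra2b 2 and Tra2b 1, against 0.217 in control. The differences for replication-dependent histones were -1.65, -1.41 and 0.269 in the same order, and for G2/M genes -1.15, -1.24 and 0.146. Cholesterol genes differed by -0.677, -0.937 and 0.047, and stress response genes by 0.321, 0.304 and -0.0692. With Serpine1 2 and Tra2b 2 left out, an alternative chosen after the data were seen, 3571 genes passed for Serpine1 against control, 4695 for the libraries labelled Tra2b overexpression against control and 5010 for Serpine1 against these libraries. That fit takes its spread from the control libraries alone and assumes that the lone libraries vary like them. Of the 47 interferon-stimulated genes, 45 and 46 still fell against control in it.

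**Figure D5:**
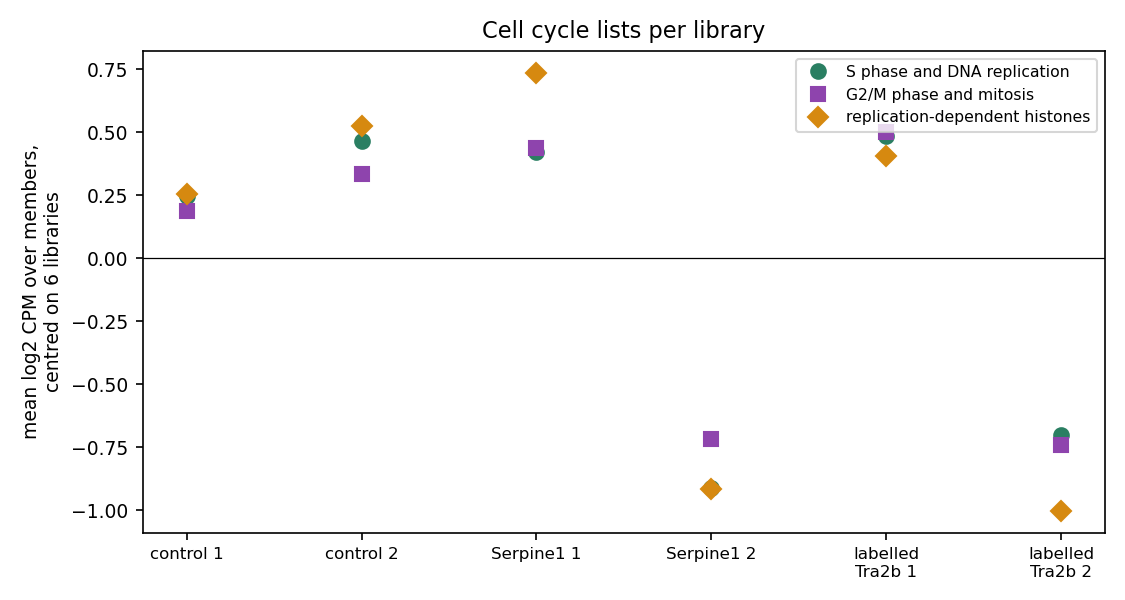
Mean log2 CPM of the members of 3 cell cycle lists in each library, centred on the mean of the 6 libraries. Serpine1 2 and Tra2b 2 lay below 0 for all 3 lists, and the other 4 libraries above 0.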

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

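In this part Tra2b as a group stands for the libraries labelled Tra2b overexpression, in which Tra2b was not raised. The replicate block and the other alternatives fixed before the data were examined were run for all results. Serpine1 2 and Tra2b 2 left out together, the cell cycle covariate, the crossed replicate block and the split of the controls between the comparisons were chosen after the data were seen. Serpine1 against control stayed called in every setting, with log2 fold changes from 2.75 to 2.95, and Tra2b was not called in any comparison or setting. None of the called named genes turned direction in any setting, and 9 of 19, 28 of 51 and 33 of 55 kept their call in all settings in Serpine1 against control, Tra2b against control and Serpine1 against Tra2b. Il11 in Tra2b against control had no value with the stricter filter, and Rnu12 in Serpine1 against control none with small RNA genes left out. The interferon-stimulated genes lower than control were 35 to 46 of 47 with Serpine1 and 46 to 47 in the libraries labelled Tra2b overexpression over the settings. The replicate block gave 248, 1385 and 1514 genes for the 3 comparisons, but correlations over genes of the replicate differences (-0.106 between control and Serpine1, -0.051 between control and Tra2b, 0.33 between Serpine1 and Tra2b) give no ground for pairing control with the others by number. With the control numbers crossed the counts were 470, 2645 and 3110, with 324 genes shared between the comparisons against control.

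Counts of genes called in Serpine1 against control, Tra2b against control and Serpine1 against Tra2b (227, 1195 and 1252) moved beyond 1.5 times as follows. DESeq2 gave 393, 1961 and 2258, the crossed replicate block 470, 2645 and 3110, the cell cycle covariate 1651, 4331 and 5365, and the omission of Serpine1 2 and Tra2b 2 gave 3571, 4695 and 5010. That last fit takes its spread from the control libraries alone, and a fit with 1 library left out takes it from the other groups. A log2 fold change of at least 1 left 785 for Tra2b against control and 656 for Serpine1 against Tra2b, and only the 4 libraries compared gave 404 for the latter, from a fit with fewer samples. With 1 library left out the ranges were 121 to 239, 369 to 1623 and 401 to 1308. The 215 shared genes became 1059 without Serpine1 2 and Tra2b 2, 713 with the covariate, 324 with the crossed block, 116 to 207 with 1 library left out, and 148 and 117 with 1 control library for each comparison. Apart from the smaller sets of libraries, the cause was not tested.

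The 8 lists called in Serpine1 against control became 4 with DESeq2, 13 with limma-voom, 2 with an estimated correlation, 2 with fry and 5 to 11 with 1 library left out. The 6 in Tra2b against control became 11 with limma-voom, 2 with an estimated correlation, 13 without Serpine1 2 and Tra2b 2, and 6 to 11 with 1 library left out. The 8 in Serpine1 against Tra2b became 0 with an estimated correlation and 5 with fry. The S phase list in Serpine1 against control turned direction without Serpine1 2 and Tra2b 2 (adjusted p = 0.168), and its adjusted p ran from 1.17e-17 to 0.381 with 1 library left out, since the list was low in Serpine1 2 alone of that group.

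Serpine1 in Tra2b against control passed with the covariate (log2 fold change -0.33, adjusted p = 0.00803) and with the crossed block (-0.43, adjusted p = 0.0197), and ran from -0.66 to -0.20 with 1 library left out. Tra2b in Serpine1 against control turned to 0.053 without Serpine1 2 and Tra2b 2 and ran from -0.31 to 0.039 with 1 library left out. In Serpine1 against Tra2b it ran from -0.091 to 0.27. Of the transition genes in Serpine1 against control, Cdh1 turned to -0.069 without Serpine1 2 and Tra2b 2 and -0.018 with the covariate (-0.083 to 0.23 with 1 library left out), and Fn1 to -0.12 without those libraries (-0.14 to 0.83). Snai2 turned to -1.10 (adjusted p = 0.00222) and -0.77 (adjusted p = 0.0365) in those settings (-1.11 to 1.17), and Cdh2 ran from -0.22 to 0.073. With the covariate, Vim also passed in that comparison, Cdh1, Fn1 and Snai2 in Tra2b against control, and Cdh1, Fn1 and Vim in Serpine1 against Tra2b. The covariate was lowest in Serpine1 2 and Tra2b 2, so it and their omission are not separate support. In Tra2b against control, Zeb1 ran from -0.22 to 0.057 and Snai2 from -1.23 to 0.60, and in Serpine1 against Tra2b Snai2 ran from -1.05 to 1.67. The cause was not tested. Depth limits little here except for genes near 0 counts, while 2 libraries per group limit the precision of all others. Epcam and Esrp1 reached at most 0.0528 and 0.0344 CPM in any library, so both were close to absent in all groups, control included.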

Other observations

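The tests of explanations in this part, with their bounds, were chosen after the results were seen, and so were the genes named in it apart from Serpine1 and Tra2b, while the comparisons against control and the RLE, library total and thinned settings were planned. Of the interferon genes, Ifnb1 stood at 2.28 and 1.79 CPM in control 1 and control 2, had 2 counts in both Serpine1 libraries together and none in the libraries labelled Tra2b overexpression. Ifna4 stood at 0.366 and 0.358 CPM in control, again with 2 counts and none. The receptor chain Ifnar1 and the transcription factor Irf3, which act upstream of the response, had log2 fold changes against control between -0.04 and 0.18, none of them called. Ifnar1 stood at 28.3 and 29.5 CPM in control, 32.5 and 33.0 CPM with Serpine1 and 30.1 and 33.0 CPM in the libraries labelled Tra2b overexpression, and Irf3 at 26.9 and 25.6, 31.4 and 24.7, and 25.3 and 25.6 CPM. Stat1, which carries the interferon signal and is induced by it, fell from 500 and 428 CPM in control to 33.8 and 35.8 CPM with Serpine1 and 16.6 and 13.2 CPM in the libraries labelled Tra2b overexpression. In replicate 2 against replicate 1, Cth stood at 42.7 against 12.7 CPM with Serpine1 and 36.7 against 13.3 CPM in the libraries labelled Tra2b overexpression, with 14.7 against 18.3 CPM in control. This is 1 gene picked for its values, without a test.

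The libraries labelled Tra2b overexpression lacked some transcripts entirely. Of 31 genes with at least 2 CPM in control and no count in these libraries, 25 were also called lower with Serpine1 and 6 were not. Rpl31-ps12, a ribosomal protein pseudogene, stood at 27.7 and 27.8 CPM in control and 22.9 and 15.3 CPM with Serpine1, and was at least 1430-fold lower than control, against a floor of 3 counts over both libraries. Luzp2 stood at 3.05 and 3.13 CPM in control and 2.13 and 1.90 CPM with Serpine1, and was at least 159-fold lower. The atypical cadherin Fat4 stood at 5.16 and 5.28 CPM in control and had 6 counts in these libraries together. The neutrophil protein S100a8 (log2 fold change 2.42, adjusted p = 0.000255), the haemoglobin scavenger Hp (2.48, adjusted p = 0.00126) and Krt16 (1.46, adjusted p = 0.0256) rose against control there. So did 29 features without a symbol, while 98 such features fell. Of the 29, 8 rose at least 4-fold with at least 10 CPM there and were not called with Serpine1. Their rises ran from 4.78-fold to 6.73-fold. Among them were GSMG0046042 (mm39 chromosome 6, 41175167 to 41178778) and GSMG0027975 (mm39 chromosome 19, 4112439 to 4116104).

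Interferon-stimulated genes were highest in control, lower with Serpine1 and lowest in the libraries labelled Tra2b overexpression. Members with at least 10 CPM in control and under 2% of the control mean in the libraries labelled Tra2b overexpression were taken. Not all were absent from the latter, where Parp14 stood at 1.1 CPM. If the Serpine1 cells had none of these transcripts, a mixture of control cells would keep 1 ratio for all of them. Over 25 such members the 90th percentile of the ratio of Serpine1 to control was 6.48 times the 10th (8.18% against 1.26% of control). It was 6.36 and 6.26 times in the single libraries. This spread argues against a mixture as the only source of these transcripts in the Serpine1 libraries. A mixture beside expression by the Serpine1 cells themselves cannot be told apart, since no unmixed Serpine1 cells were measured. The scaling between libraries is argued against too, since the TMM factors ran only from 0.9456 to 1.031. The median falls of the list were 12.96-fold with Serpine1 and 97.72-fold in the libraries labelled Tra2b overexpression. At least 44 of 47 members stayed lower than control with RLE factors and with library totals, which scaling differences this small could hardly have changed. An interferon response that arose in the control cultures for another reason cannot be told apart from an action of the introduced genes or of the viruses, since Ifnb1 (mean 2.04 CPM) was counted in control and the labels name no further control. An exchange of control with the libraries labelled Tra2b overexpression, left open below, would turn the direction with Serpine1. Against the latter libraries 37 of 47 members were higher with Serpine1 and none lower. An action of the introduced Serpine1 or of the Tra2b construct remains open as a hypothesis, which the data at hand do not test.

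Tra2b was not higher in the libraries labelled Tra2b overexpression. An exchange with libraries labelled Serpine1 overexpression is argued against, since the lower of those had 6.71 times the Serpine1 level of the highest other library. An exchange with control cannot be told apart: the highest of the 6 libraries had 1.12 times their median Tra2b level, but no library would show a raised level if the introduced sequence was not counted at the Tra2b gene. An introduced Tra2b sequence that was not counted at the Tra2b gene stays open, since the upper end of the 95% interval of the fold was 1.07 and the table holds no counts below the level of the gene. A loss of the construct or a fall of the cell's own Tra2b was not tested.

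Cell cycle genes were lower in replicate 2 than in replicate 1 of the Serpine1 libraries and those labelled Tra2b overexpression, and not in control. Depth is argued against, since Serpine1 2 had more counts than Serpine1 1 (72401414 and 61462018) and Tra2b 2 fewer than Tra2b 1 (73425150 and 80876677). In libraries thinned to 1 total the S phase difference closest to 0 was still -1.2. Loss of RNA without poly(A) tails is argued against, since the S phase genes, whose mRNAs carry such tails, differed by -1.33 and -1.18, beside the histones. A shared handling or culture state of these cultures, such as their density, cannot be told apart from separate events, since no label records handling. The replicate differences of both groups correlated over all tested genes (r = 0.33). Those genes include the cell cycle genes themselves, so the correlation partly restates the pattern and is no support for a shared state. Genes are also not independent replicates. The groups give no biological explanation for a difference within a group, and none was tested.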
